A study of Mus musculus with 4 samples.

How the data were processed

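The series measured RNA in single nuclei from a block of mouse hindbrain that holds the area postrema and the nucleus of the solitary tract, brainstem sites that receive feeding-related signals from the blood and the vagus nerve. The animals were C57BL/6 mice aged 6 to 8 weeks. One group of 6 mice had free access to food and another group of 6 mice went 16 h without food. Per the labels' protocols, nuclei were released with a dounce homogeniser, purified by flow sorting and captured with the 10x Chromium 3' kit, version 3. That kit tags each captured RNA molecule with a unique molecular identifier (UMI). There were 4 libraries, 2 from fed and 2 from fasted mice. How many mice entered each library, and whether fed and fasted tissue was handled together, is not given in the sources used here.

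The authors aligned and counted the reads with Cell Ranger 4.0 on the GRCm38 mouse genome, per the submitters' processing notes, and the deposited matrices hold a whole-number UMI count for each gene and barcode. Whether reads in introns were counted is not given in the sources used here. The 4 matrices held 16912 barcodes and 55401 genes, of which 55141 matched the GENCODE vM21 annotation by identifier. Total UMIs were 24918895 and 29146545 in the fed libraries and 25362169 and 27882870 in the fasted ones. The precision of a gene's value in a class depends on the nuclei behind it, which ranged from 8959 neurons to 91 fibroblasts. Intervals and floors for counts of 0 cover counting error only.

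Barcodes with at least 500 detected genes and under 5% mitochondrial UMIs were kept, which removed 72. Doublets were scored per library with the Scrublet method in scanpy 1.11.5, and the highest-scoring nuclei were removed at a rate of 0.8% per 1000 nuclei, which was 574 nuclei or 3.41%. Scrublet's own threshold called 396. The remaining 16266 nuclei were scaled to 10000 UMIs, log-transformed, reduced to 3000 variable genes and 30 principal components, and clustered by the Leiden method with 15 neighbours and a resolution of 1.0. This gave 29 clusters. Classes were named from marker genes fixed before the data were examined, and a name needed at least 3 markers. The names are therefore rebuilt here and rest on those markers. A cluster of 51 nuclei stayed unnamed. Neurons were clustered again, into 35 neuronal clusters. The tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9.

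Counts were summed over the nuclei of each class in each library, so that libraries and not nuclei were the replicates. Each class with at least 20 nuclei in every library was compared between fed and fasted with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter on low counts and Benjamini-Hochberg adjustment at 0.05. The same test was run on single neuronal clusters, with adjustment over all clusters and genes together. A difference in the effect of fasting between classes was tested as an interaction, with the library as a block. Levels are given in CPM, in which counts are scaled to the same library total, as the mean and SD of the 2 libraries of a group. The p-values measure only the spread between libraries, which may be technical, with 2 residual degrees of freedom in each class. The edgeR test draws the variance of each gene toward a trend over all genes. Its p-values therefore do not rest on the gene's own spread alone, and a gene with a wide SD can have a small p.

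The gene lists were also fixed before the data were examined. There were 19 lists, and a list was tested in a class where at least 5 of its members were measured, which gave 73 tests. They were tested with camera in limma 3.58.1 on voom values with a preset correlation between genes of 0.01, two-sided and adjusted over the 73 tests. Members were also adjusted over the list alone. The share of nuclei in each class was tested with edgeR on nuclei counts and with an exact permutation test over libraries, whose smallest two-sided p in this design is 0.333. Receptor and peptide transcripts were mapped over neuronal clusters as the share of nuclei with at least 1 UMI. As background, the same share was taken in oligodendrocytes, and both were repeated with each nucleus thinned to 2000 UMIs.

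The genes named in the text followed a rule set at the same time. It took genes past the threshold whose fasted libraries both lay above or both below the fed libraries and whose mean was at least 10 CPM. Among these it took the 12 with the largest change in each direction in the 3 classes with the most calls and 4 in each direction in the others. Predicted genes and clone names were passed over. It added the members past the threshold of each called list, or the 4 with the smallest p where none passed. It also added all measured appetite-related receptors and neuropeptides in neurons, and the 5 genes with the smallest p in a class with no call. Genes named outside the rule are said to be chosen after their values were seen.

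The tests were tested on simulated data in which 200 genes (199 for the interaction) were given known changes in counts drawn from the real means. In neurons 76.1% of genes changed 2-fold were recovered, in oligodendrocytes 70.1%, in astrocytes 40.3%, in oligodendrocyte precursors 43.3% and in microglia 19.4%. For the interaction of oligodendrocytes and neurons the value was 67.2%. Between 2 and 10 unchanged genes were called in each.

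The alternatives fixed before the data were examined were DESeq2 1.42.0, size factors by the median ratio (RLE), no filter on low counts or a minimum of 50 counts, a replicate block, leaving out each library in turn, thinning libraries to equal totals, keeping doublets, a stricter filter on nuclei (1000 genes and 1% mitochondrial UMIs), a cluster resolution of 2.0, and for lists an estimated correlation or fry. Others were chosen after seeing the data. These were a test against a 1.5-fold change, equal numbers of nuclei per neuronal cluster in every library, voom weights capped at the 99th percentile, a crossed pairing in fibroblasts and a clustering of neurons without the genes that differed. The voom weights were capped because a few weights in oligodendrocyte precursors were extreme, which left the planned list tests in that class without meaning. Choroid plexus and endothelial nuclei and the unnamed cluster were too few to test for genes. No correction for free RNA was made. A test of where the RNA of Ptgds came from is not reported here.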

Results

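Nuclei from the fed and fasted hindbrain were profiled in 4 libraries. The fed libraries held 3524 and 4565 barcodes and the fasted libraries 4100 and 4723. The median depth was 5641.5 and 5069 UMIs per barcode in the fed libraries and 4846.5 and 4714 in the fasted ones. After filtering, 3411 and 4383 fed nuclei and 3947 and 4525 fasted nuclei were used. Neurons made up 55.1% of these nuclei and oligodendrocytes, the myelin-forming cells, 33.6%. Astrocytes made up 3.87%, oligodendrocyte precursors 3.31% and microglia, the resident immune cells, 2.39%. Committed oligodendrocyte precursors, which are on the way to becoming myelinating cells, made up 0.744%, fibroblasts 0.559%, choroid plexus cells 0.0799% and endothelial cells 0.0738%.

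To ask whether the makeup of the tissue differed after the fast, the share of each class was compared. Microglia made up 1.84 ± 0.0522% of nuclei in the fed libraries and 2.92 ± 0.498% in the fasted libraries (mean ± SD, 2 libraries per group), a log2 ratio of 0.66 with a standard error (SE) of 0.15. Choroid plexus nuclei, which come from the tissue that secretes cerebrospinal fluid, made up 0.161 ± 0.0623% of fed nuclei. None were found among 8472 fasted nuclei, which allows a share of up to 0.0354%. Both shares passed the edgeR test (adjusted p = 0.00218 for each), and the exact permutation test gave the smallest two-sided p this design allows, 0.333. Neurons (55.6 ± 1.32 and 54.7 ± 0.0830%), oligodendrocytes (33.5 ± 1.32 and 33.6 ± 0.2499%) and astrocytes (3.75 ± 0.134 and 3.99 ± 0.266%) did not pass. Without the first fasted library no share passed, without the second only that of microglia, and with the stricter filter on nuclei only that of the choroid plexus. Dissection and sorting can set these shares, and Ttr, which defines choroid plexus nuclei, was also lower in fasted nuclei of other classes.

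The effect of the fast on oligodendrocytes was examined in 5463 nuclei. Genes that glucocorticoid hormones are known to induce were higher in the fasted libraries. Plin4, which encodes a coat protein of lipid droplets, rose from 2.81 ± 0.440 to 63.1 ± 8.18 CPM, a log2 fold change of 4.47 (SE 0.21; edgeR adjusted p = 1.36e-26). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 18.4 ± 0.436 to 147 ± 7.62 CPM (2.99 on the log2 scale, SE 0.11; edgeR adjusted p = 1.24e-31). Sgk1, a kinase named for its regulation by serum and glucocorticoids, rose from 44.2 ± 0.722 to 280.0 ± 7.399 CPM (2.66, SE 0.08; edgeR adjusted p = 1.28e-36). Hif3a, a hypoxia-inducible factor, rose from 7.20 ± 0.476 to 80.1 ± 4.83 CPM (3.46, SE 0.16; edgeR adjusted p = 3.03e-27), and the transcription factor Zbtb16 rose from 135 ± 6.91 to 371 ± 6.84 CPM (1.46, SE 0.06; edgeR adjusted p = 8.11e-30). On GRCm38, Plin4 (ENSMUSG00000002831) lies on chromosome 17 from 56100591 to 56109803, Fkbp5 (ENSMUSG00000024222) on chromosome 17 from 28399094 to 28517527, Sgk1 (ENSMUSG00000019970) on chromosome 10 from 21882184 to 21999903, Hif3a (ENSMUSG00000004328) on chromosome 7 from 17031507 to 17062427 and Zbtb16 (ENSMUSG00000066687) on chromosome 9 from 48654297 to 48836222. Fkbp5 overlaps the predicted genes AC154912.5 and AC154912.3 on its strand, and whether its counts include reads of theirs was not tested.

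Of 21 glucocorticoid-responsive genes measured in oligodendrocytes, 17 rose and none fell. With p adjusted over the list alone 18 rose and 1 fell. The median log2 fold change of the list was 1.52 (camera adjusted p = 3.55e-30; adjusted p = 0.432 with an estimated correlation). Among the other risen members were Nfkbia, an inhibitor of NF-kappa B (12.6 ± 0.989 to 53.9 ± 1.34 CPM), Ddit4, an inhibitor of mTORC1 (26.9 ± 9.36 to 87.8 ± 6.02 CPM), Mt1, a metallothionein (23.5 ± 4.23 to 81.3 ± 0.514 CPM) and the transcription factor Klf9 (92.8 ± 1.53 to 177 ± 8.44 CPM). Sult1a1 was at 0.286 ± 0.0368 CPM in fed and 5.53 ± 0.829 CPM in fasted oligodendrocytes. Outside the list, the hedgehog effector Gli2 (3.64), the integrin gene Itgad (3.20), Zfand4 (2.79), Scrg1 (2.62), the TGF-beta effector Smad3 (2.36), Sh2b2 (2.11) and Pdk4, a kinase that shuts down pyruvate oxidation (2.13), were among the largest log2 increases. Itgad overlaps Gm17831, and its reads are uncertain.

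**Figure D1:**
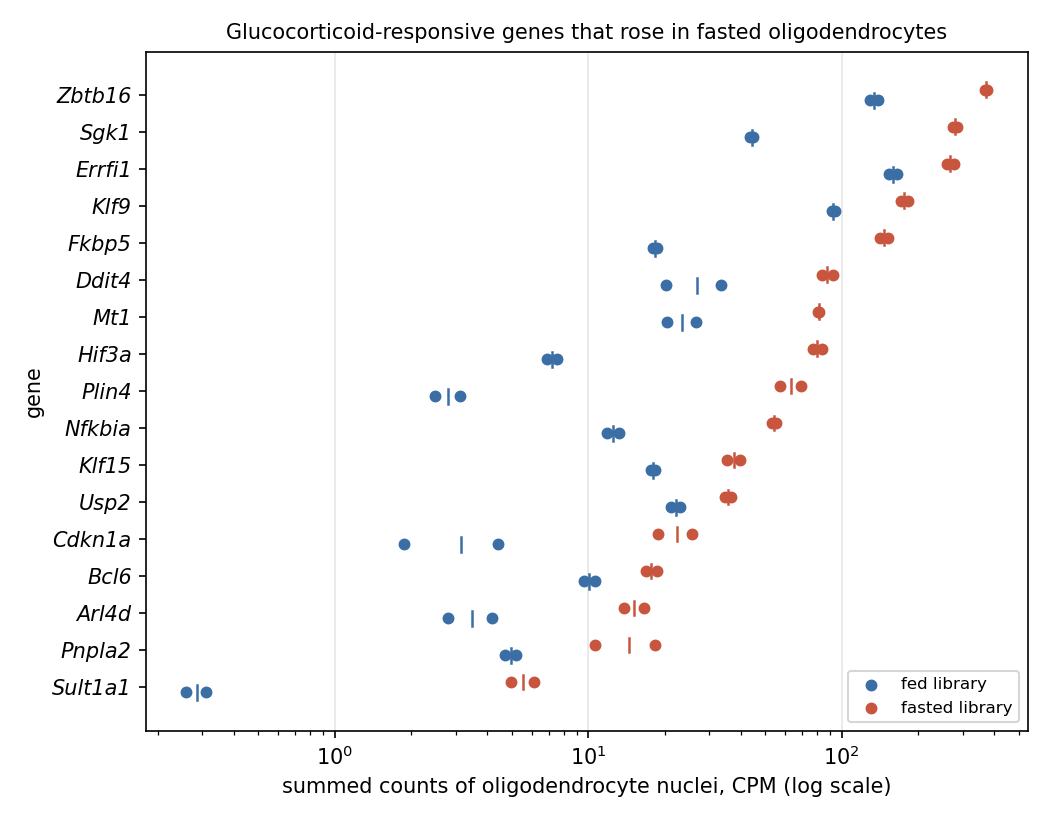
Summed counts of oligodendrocyte nuclei in CPM (horizontal, log scale) for the 17 glucocorticoid-responsive genes that rose. Each point is a library, short lines mark group means, and in each of the 17 genes both fasted libraries (red) lie above both fed libraries (blue).

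Protein-folding genes were lower in fasted oligodendrocytes. Hspa5, the main chaperone of the endoplasmic reticulum (ENSMUSG00000026864, chromosome 2 from 34771970 to 34777547), fell from 60.4 ± 1.23 to 22.8 ± 0.654 CPM, a log2 fold change of -1.41 (SE 0.13; edgeR adjusted p = 7.51e-14). Its partners Hsp90b1 (88.9 ± 9.25 to 44.9 ± 3.80 CPM) and Calr (40.2 ± 3.58 to 21.3 ± 2.96 CPM) fell as well. Of 16 measured genes of the endoplasmic reticulum and integrated stress response, 8 fell and 2 rose, both over all genes and adjusted over the list alone. The 2 that rose were Psat1, an enzyme of serine synthesis (61.1 ± 4.46 to 83.0 ± 3.31 CPM), and Herpud1, which takes part in the breakdown of misfolded proteins (29.4 ± 1.02 to 39.6 ± 0.824 CPM). Herpud1 did not pass with DESeq2 (adjusted p = 0.342) or, with edgeR, in any of the 4 fits that left out a library (adjusted p from 0.0721 to 0.134). The list's median was -0.33 (camera adjusted p = 0.0363; adjusted p = 0.790 with an estimated correlation), and the list did not pass without the first fed library (camera adjusted p = 0.178), without the first fasted library (0.284) or without the second fasted library (0.0648). Of 17 cytosolic heat shock chaperones 8 fell, or 10 adjusted over the list alone, with a median of -0.47 (camera adjusted p = 1.78e-06; adjusted p = 0.606 with an estimated correlation). Hsp90ab1 fell from 217 ± 3.94 to 119 ± 6.03 CPM, Hsp90aa1 from 71.7 ± 8.84 to 45.4 ± 5.71 CPM and Cryab from 229 ± 15.8 to 154 ± 0.424 CPM.

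Genes of lipid synthesis were also lower. Of 24 genes of cholesterol synthesis 12 fell in oligodendrocytes, and adjusted over the list alone 12 fell and 1 rose. The median was -0.38 (camera adjusted p = 2.35e-05; adjusted p = 0.606 with an estimated correlation). Hmgcs1, which makes HMG-CoA, fell from 81.2 ± 4.25 to 49.8 ± 6.50 CPM. Msmo1 fell from 137 ± 4.15 to 96.1 ± 1.64 CPM and Fdps from 17.5 ± 1.255 to 7.72 ± 0.615 CPM. Of 19 genes of fatty acid and sphingolipid synthesis 8 fell and 1 rose, or 9 and 1 adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.00266; adjusted p = 0.606 with an estimated correlation). Ugt8a, which makes the myelin lipid galactosylceramide, fell from 689 ± 22.2 to 438 ± 20.3 CPM and the fatty acid elongase Elovl6 fell from 118 ± 0.805 to 80.0 ± 0.546 CPM. Acaca, which makes malonyl-CoA, rose from 494 ± 3.67 to 666 ± 12.2 CPM. Outside these lists Mob3b (308 ± 7.402 to 121 ± 2.58 CPM), the growth factor Vegfa (20.1 ± 1.18 to 7.34 ± 1.56 CPM), and Etv5 and Spry2, a target and an inhibitor of receptor tyrosine kinase signalling, fell by 1.63 and 1.35 on the log2 scale.

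In oligodendrocytes edgeR called 843 genes higher and 1045 lower in the fasted libraries out of 12702 tested. DESeq2 called 808, and a test against a 1.5-fold change, chosen after seeing the data, called 181. RNAs that are kept in the nucleus, chosen after their values were seen, were among the lower ones: Neat1 (-0.45), Meg3 (-0.22), Snhg11 (-0.13) and Malat1 (-0.06 on the log2 scale), with edgeR adjusted p = 8.29e-19, 4.64e-07, 0.00626 and 0.00273, while Snhg14 did not pass (-0.17, edgeR adjusted p = 0.226). Different clusters held most oligodendrocytes in the 2 groups: clusters 2 and 3 held 22.4 and 61.3% of fed oligodendrocytes, and clusters 4 and 5 held 50.02 and 32.1% of fasted ones. These clusters were formed with the genes that differed.

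**Figure D2:**
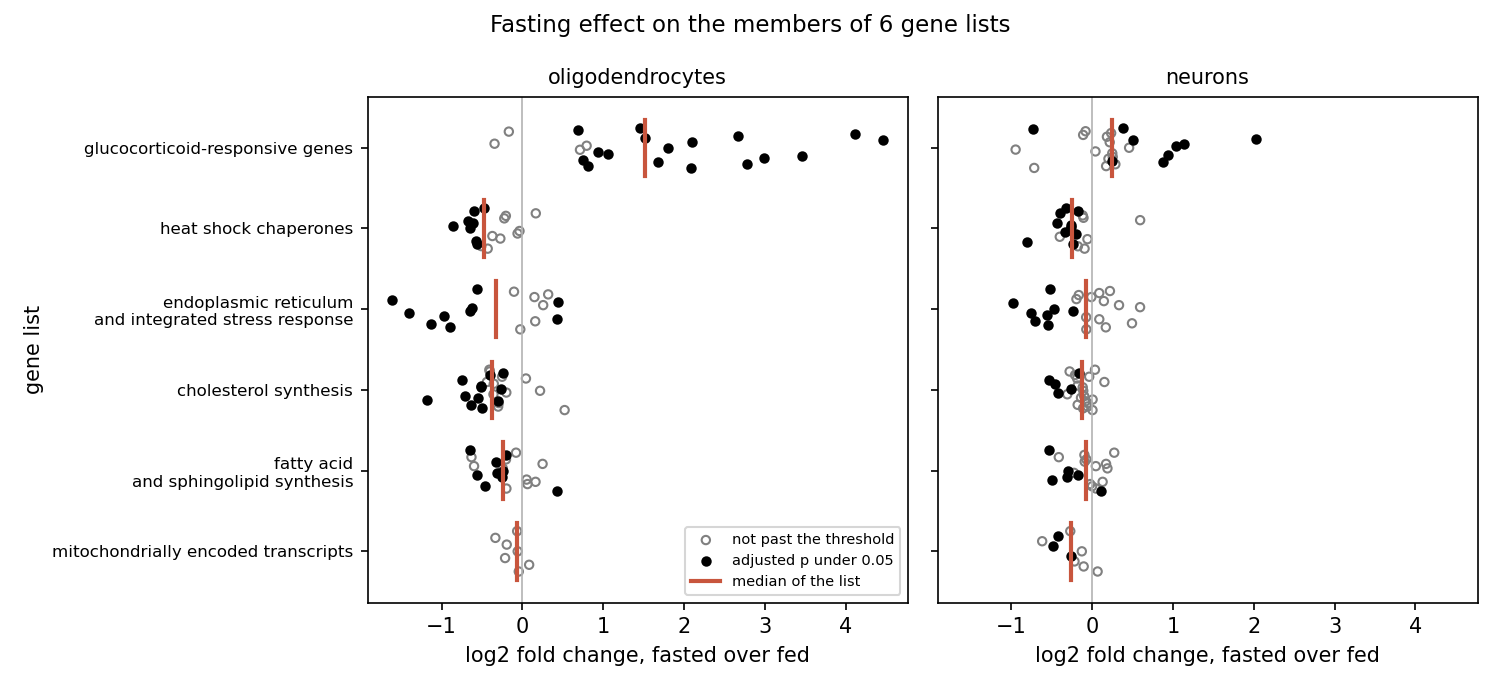
Log2 fold change (fasted over fed, horizontal) of each measured member of 6 gene lists in oligodendrocytes (left) and neurons (right). Filled points passed edgeR's adjusted threshold of 0.05 and red bars are list medians, which lie at 1.52 and 0.25 for the glucocorticoid-responsive genes.

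Neurons were examined in 8959 nuclei, where changes were smaller. Srsf10, a splicing regulator (ENSMUSG00000028676, chromosome 4 from 135855747 to 135869908), rose from 91.9 ± 0.660 to 151 ± 0.689 CPM, a log2 fold change of 0.72 (SE 0.03; edgeR adjusted p = 1.21e-08). Zmym1, a zinc finger gene (ENSMUSG00000043872, chromosome 4 from 127047094 to 127061152), fell from 78.5 ± 5.396 to 38.3 ± 1.73 CPM (-1.04, SE 0.06; edgeR adjusted p = 2.90e-08). Ptgds, which encodes prostaglandin D synthase, rose from 98.2 ± 16.7 to 201 ± 4.47 CPM, the homeobox gene Hoxc4 from 23.2 ± 0.3499 to 35.4 ± 1.65 CPM and the protease gene Htra1 from 9.96 ± 0.2003 to 18.1 ± 0.917 CPM. Lower genes included the transcription factors Foxp2 (65.0 ± 0.639 to 32.4 ± 1.85 CPM) and Nr2f2 (27.8 ± 1.52 to 13.8 ± 1.32 CPM), and Tph2, the enzyme of serotonin synthesis in neurons (18.7 ± 8.71 to 3.79 ± 2.16 CPM). Sox2ot, which overlaps Sox2 and is uncertain for that reason, fell by 1.44 on the log2 scale.

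Several lists that differed in oligodendrocytes also differed in neurons. Of 18 heat shock chaperones 11 fell in neurons, or 12 adjusted over the list alone, with a median of -0.25 (camera adjusted p = 4.45e-08; adjusted p = 0.606 with an estimated correlation). Cryab fell from 13.8 ± 1.69 to 7.95 ± 0.873 CPM, Hsph1 from 33.96 ± 0.331 to 25.8 ± 0.278 CPM and Hsp90ab1 from 95.4 ± 3.58 to 79.9 ± 3.22 CPM. Of 21 genes of the endoplasmic reticulum and integrated stress response 8 fell, also adjusted over the list alone, with a median of -0.07 (camera adjusted p = 0.0118; adjusted p = 0.606 with an estimated correlation). These included Hspa5 (36.7 ± 2.70 to 21.7 ± 0.384 CPM), Hsp90b1 (61.6 ± 3.76 to 42.0 ± 0.926 CPM) and Xbp1, a transcription factor of this response (29.7 ± 1.06 to 20.6 ± 0.286 CPM). Of 24 genes of cholesterol synthesis 5 fell, or 11 adjusted over the list alone, with a median of -0.13 (camera adjusted p = 2.00e-04; adjusted p = 0.606 with an estimated correlation). Nsdhl fell from 30.01 ± 0.932 to 20.7 ± 1.57 CPM. Of 23 glucocorticoid-responsive genes 8 rose and 1, Usp2, fell, or 10 and 2 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.00332; adjusted p = 0.606 with an estimated correlation). Mt1 rose from 12.1 ± 1.97 to 24.9 ± 0.737 CPM, Ddit4 from 3.94 ± 0.0494 to 7.21 ± 0.186 CPM and Plin4 from 0.486 ± 0.0403 to 2.00 ± 0.102 CPM. Fkbp5 (27.8 ± 1.18 and 32.1 ± 2.08 CPM; edgeR adjusted p = 0.0640) and Sgk1 (104 ± 3.13 and 96.1 ± 0.325 CPM; edgeR adjusted p = 0.0625) did not pass.

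Of 9 mitochondrially encoded transcripts 3 fell in neurons, also adjusted over the list alone: mt-Nd2 (22.1 ± 0.429 to 15.8 ± 0.786 CPM), mt-Nd4 (22.9 ± 2.17 to 17.1 ± 1.28 CPM) and mt-Cytb (43.5 ± 2.75 to 36.2 ± 0.00926 CPM). The list's median was -0.26 (camera adjusted p = 0.00761; adjusted p = 0.606 with an estimated correlation), and it did not pass without the first fasted library (camera adjusted p = 0.0578). mt-Nd4 overlaps mt-Nd4l and did not pass with DESeq2 (adjusted p = 0.0724), and mt-Cytb did not pass with DESeq2 (0.141) or with edgeR without the first fed library (0.0676). Mitochondrial RNA lies outside the nucleus, and the median share of mitochondrial UMIs per barcode was 0.0197 and 0.0177% in the fed libraries and 0.0136 and 0.0132% in the fasted ones. Some transcripts of oligodendrocytes also differed in neuronal nuclei. Gjc3 (19.1 ± 0.877 to 12.7 ± 0.735 CPM), Mag (35.1 ± 0.849 to 28.3 ± 0.428 CPM) and Ugt8a (25.8 ± 0.0870 to 17.8 ± 0.973 CPM) fell in neurons, and Mobp (19.3 ± 2.51 to 23.8 ± 0.761 CPM) rose, each in the direction of its change in oligodendrocytes. These 4 were chosen after their values were seen. Of 20 genes of myelin structure and oligodendrocyte identity 3 rose and 4 fell in neurons, or 4 and 4 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.989).

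In neurons edgeR called 1109 genes higher and 1434 lower in the fasted libraries out of 19361 tested. DESeq2 called 746, and the test against a 1.5-fold change called 34. Of the RNAs kept in the nucleus, Meg3 (-0.17) and Snhg11 (-0.08) fell in neurons as well (edgeR adjusted p = 1.81e-06 and 0.00515), and Neat1, Snhg14 and Malat1 did not pass (0.0525, 0.104 and 0.505). The neuronal clusters were unevenly represented in the 2 groups, and with equal numbers of nuclei per cluster (1565 nuclei per library) 1419 genes were called, 1290 of them among the first set. Of the calls in the lists above, 8 of 11 heat shock chaperones, 7 of 8 genes of the endoplasmic reticulum and integrated stress response, 3 of 5 of cholesterol synthesis, 7 of 9 glucocorticoid-responsive, 3 of 3 mitochondrially encoded and 3 of 7 myelin genes passed with clusters matched. Zmym1 (-1.17), Hspa5 (-0.85) and Srsf10 (0.66) kept their call with clusters matched. Sox2ot (-0.74, from -1.44), Nr2f2 (-0.57, from -1.01) and Hoxc4 (0.37, from 0.61) passed with smaller changes. The fall of Foxp2 then measured -0.26 on the log2 scale (edgeR adjusted p = 0.0175), and that of Tph2 measured -0.61 and did not pass (edgeR adjusted p = 0.127).

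**Figure D3:**
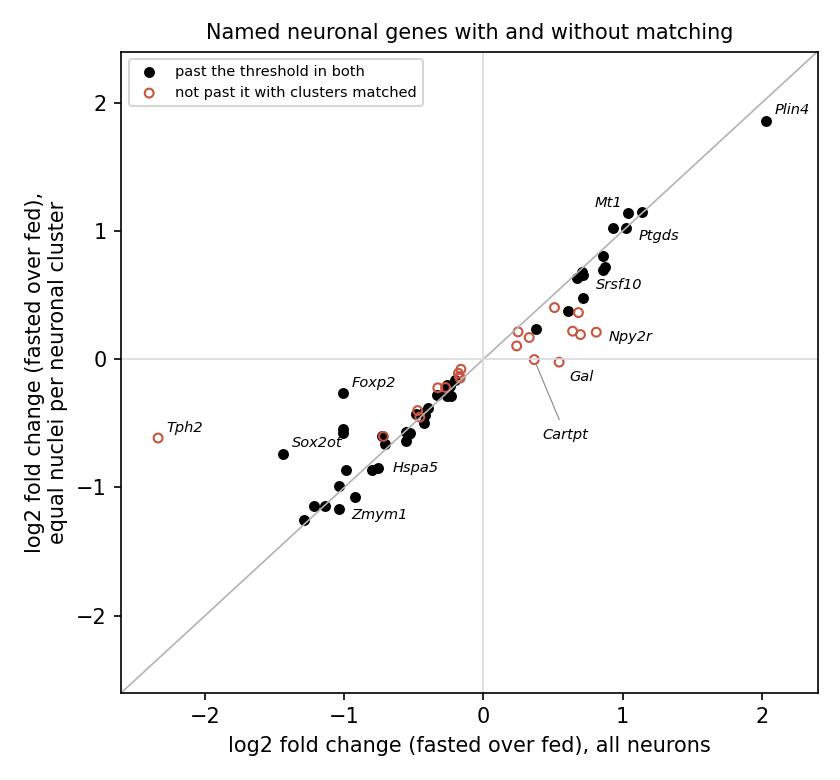
Log2 fold change (fasted over fed) of the named neuronal genes past the threshold, from all neurons (horizontal) and from equal numbers of nuclei per neuronal cluster (vertical). Ttr, at -5.30 from all neurons, is outside the range. Gal, Cartpt, Npy2r and Tph2 lie well off the diagonal, while Plin4, Mt1, Hspa5 and Zmym1 lie near it.

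Because the tissue controls feeding, the genes for appetite-related receptors and peptides were examined in neurons. Gal, which encodes the peptide galanin, rose from 11.8 ± 0.871 to 17.2 ± 1.06 CPM (edgeR adjusted p = 0.00128). Penk, which encodes enkephalins, rose from 35.5 ± 0.853 to 44.6 ± 3.88 CPM (edgeR adjusted p = 0.00305), and Cartpt, which encodes the CART peptides, from 13.9 ± 0.217 to 17.9 ± 1.02 CPM (edgeR adjusted p = 0.0103). Gcg, the precursor of GLP-1, fell from 3.92 ± 0.668 to 2.38 ± 0.224 CPM (edgeR adjusted p = 0.0320). Among receptors, the neuropeptide Y receptor gene Npy2r rose from 1.73 ± 0.383 to 3.03 ± 0.292 CPM (edgeR adjusted p = 0.0345), the mu-opioid receptor gene Oprm1 rose from 62.0 ± 1.24 to 73.1 ± 4.09 CPM (edgeR adjusted p = 0.00383) and the serotonin receptor gene Htr2c fell from 628 ± 42.8 to 562 ± 11.4 CPM (edgeR adjusted p = 0.00676). Agrp fell by 0.18, but its annotated span of 70.7 kb overlaps Gm45855 and Gm5914, so its counts are uncertain, as are those of Htr2c, which overlaps other genes.

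Several of these appetite-related values were smaller with clusters matched. Gal and Cartpt reversed from log2 fold changes of 0.54 and 0.37 to -0.02 and -0.00308 (edgeR adjusted p = 0.941 and 0.991). The log2 fold change went from 0.81 to 0.21 for Npy2r, from 0.24 to 0.10 for Oprm1, from 0.33 to 0.17 for Penk, from -0.16 to -0.08 for Htr2c and from -0.18 to -0.11 for Agrp, and none of them passed (edgeR adjusted p = 0.720, 0.2503, 0.238, 0.207 and 0.230). Gcg went from -0.72 (SE 0.20) to -0.60 (SE 0.33) and did not pass (edgeR adjusted p = 0.327), so with the larger error of fewer nuclei it was not shown whether its change remained. DESeq2 did not call Cartpt, Gcg, Npy2r, Oprm1, Htr2c or Agrp (adjusted p from 0.0602 to 0.383). With edgeR, Cartpt did not pass without the second fasted library (adjusted p = 0.0737), and Gcg, Npy2r and Agrp did not pass without the second fed library (0.216, 0.202 and 0.226) or without the first fasted library (0.106, 0.130 and 0.0595). Of 22 receptors 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.449). Of 24 neuropeptides and transmitter enzymes 3 rose and 3 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.682). The peptide list's median was 0.10 and its mean -0.09, so the 2 differed in sign. The receptor genes Glp1r (2.42 ± 0.0733 and 2.42 ± 0.0881 CPM), Gfral (3.68 ± 0.482 and 3.57 ± 0.2499 CPM), Calcr (5.28 ± 1.14 and 5.15 ± 0.842 CPM) and Lepr (20.2 ± 2.64 and 21.5 ± 1.81 CPM) gave edgeR adjusted p = 0.996, 0.899, 0.922 and 0.616. At these levels small differences were not detectable. Of 16 immediate early genes, which mark recent neuronal activity, none passed in neurons, also adjusted over the list alone (camera adjusted p = 0.989). Of 14 late activity-dependent genes Sorcs3 rose and Vgf fell (camera adjusted p = 0.989), and neither passed with clusters matched (edgeR adjusted p = 0.401 and 0.138).

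The test was repeated within 26 single neuronal clusters to ask which changes recurred. Ptgds was higher in the fasted libraries in 26 of 26 clusters, with 18 calls and a median log2 fold change of 0.95. RNA from oligodendrocytes was not excluded for this rise, as described below. Ttr, weighed below as possible free RNA, was lower in 12 of 12 clusters with 10 calls. Zmym1 was lower in 26 of 26 with 10 calls, Las1l, a gene of ribosome assembly, higher in 26 of 26 with 9 calls, and Dalrd3 lower in 26 of 26 with 7 calls. Erbb4 also had 7 calls but went both ways, with 2 calls higher and 5 lower. Kidins220, a scaffold of neurotrophin receptors, and the splicing kinase gene Prpf4b were lower in 26 of 26 clusters with 5 calls each, and Srsf10 was higher in 26 of 26 with 4 calls. Over all clusters and genes edgeR called 191 higher and 450 lower, 641 in all. Leaving out the first fed library gave 978 calls, the second fed library 957, the first fasted library 1032 and the second fasted library 1077. Clusters 1, 2 and 4 gave the most calls. Cluster 4 held 456 fed and 54 fasted nuclei, so the groups were unequal within it. The clusters were drawn from all genes, those that differed included.

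Astrocytes were examined in 630 nuclei. Zfhx3, a transcription factor with a role in circadian timing (ENSMUSG00000038872, chromosome 8 from 107942644 to 108961630), rose from 266 ± 105 to 766 ± 108 CPM, a log2 fold change of 1.54 (SE 0.14; edgeR adjusted p = 1.01e-16). Hif3a rose from 115 ± 9.86 to 325 ± 56.8 CPM (1.501, SE 0.18; edgeR adjusted p = 1.45e-10), and the metallothionein genes Mt1 and Mt2 rose from 247 ± 49.4 to 557 ± 26.0 CPM and from 73.5 ± 0.535 to 197 ± 2.35 CPM. Grm5, a metabotropic glutamate receptor gene, fell from 398 ± 14.6 to 127 ± 10.5 CPM (-1.66, SE 0.17; edgeR adjusted p = 8.74e-14), and Cyp26b1, which degrades retinoic acid, fell from 218 ± 5.17 to 64.7 ± 10.2 CPM (-1.76, SE 0.21; edgeR adjusted p = 3.98e-10). Lpo, a peroxidase gene, fell from 70.0 ± 0.948 to 11.1 ± 1.70 CPM. Zfhx3 overlaps 3 small genes on its strand.

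Of 17 glucocorticoid-responsive genes 7 rose in astrocytes, or 10 adjusted over the list alone, with a median of 0.61 (camera adjusted p = 2.01e-12; adjusted p = 0.606 with an estimated correlation). Besides Hif3a, Mt1 and Mt2 these were Mertk, a receptor for the uptake of dying cells (324 ± 15.6 to 593 ± 39.1 CPM), Fkbp5, Zbtb16 and Errfi1. Mertk did not pass without the first fed library (edgeR adjusted p = 0.0610), and Fkbp5, Zbtb16 and Errfi1 did not pass without the first fed, the second fed or the second fasted library (edgeR adjusted p from 0.0898 to 0.629). Of 16 genes of cholesterol synthesis none passed, also adjusted over the list alone, yet the list's median was -0.44 (camera adjusted p = 0.00197; adjusted p = 0.663 with an estimated correlation). Its call was lost without the first fasted library (camera adjusted p = 0.0578). Insig1, a feedback regulator of this pathway, measured 67.1 ± 12.9 and 32.9 ± 11.5 CPM, and Hmgcs1 64.2 ± 30.1 and 33.2 ± 8.30 CPM. Of 11 genes of insulin and FOXO signalling none passed, or 3 rose adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.00626; adjusted p = 0.606 with an estimated correlation). Pik3r1, a subunit of PI3-kinase, measured 268 ± 13.3 and 368 ± 14.6 CPM. In astrocytes edgeR called 102 genes higher and 107 lower of 6990 tested. DESeq2, which gave an adjusted p for 1363 genes, called 46, and the test against a 1.5-fold change called 17. Leaving out a library gave 22 calls without the first fed, 106 without the second fed, 119 without the first fasted and 132 without the second fasted library, and thinning libraries to equal totals gave 64.

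In oligodendrocyte precursors, examined in 538 nuclei, Tes, a gene of focal adhesions, rose from 40.7 ± 0.526 to 126 ± 2.25 CPM (edgeR adjusted p = 7.32e-05) and Atg13, which starts autophagy, rose from 23.6 ± 0.789 to 81.3 ± 1.18 CPM (edgeR adjusted p = 0.00168). Ndst3, an enzyme of heparan sulfate synthesis, fell from 83.7 ± 8.22 to 25.4 ± 2.84 CPM (edgeR adjusted p = 0.00184) and the chaperone gene Hsp90b1 fell from 138 ± 13.4 to 60.5 ± 4.80 CPM (edgeR adjusted p = 0.00507). The glucocorticoid-responsive genes Zbtb16 (102 ± 14.5 to 224 ± 28.4 CPM), Mertk (104 ± 33.5 to 232 ± 39.4 CPM) and Fkbp5 (39.8 ± 15.5 to 105 ± 23.9 CPM) rose, 3 of 9 measured and 6 adjusted over the list alone. These 3 were chosen after their values were seen. With capped voom weights, an alternative chosen after seeing the data, the list passed (camera adjusted p = 1.38e-11; adjusted p = 0.508 with an estimated correlation), and the planned test, whose weights were extreme, gave 0.989. In this class edgeR called 18 genes higher and 17 lower of 6762 tested. DESeq2, which gave an adjusted p for 19128 genes, called 0, the genes named here included, with 113 at an unadjusted p under 0.05, and thinned libraries gave 6. Leaving out the first fed, second fed, first fasted and second fasted library gave 10, 6, 19 and 9 calls. Atg13 did not pass without either fed library (edgeR adjusted p = 0.0822 and 0.0913) or the second fasted one (0.0633), Ndst3 without the second fed or second fasted library (0.119 each), and Hsp90b1 in any of the 4 (0.0511 to 0.238).

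In microglia, examined in 388 nuclei, Fkbp5 rose from 234 ± 12.3 to 875 ± 103 CPM, a log2 fold change of 1.89 (SE 0.24; edgeR adjusted p = 1.51e-07). It was the one gene past the threshold among 5 glucocorticoid-responsive genes measured, also adjusted over the list alone, and the list's median was 0.50 (camera adjusted p = 6.71e-04; adjusted p = 0.606 with an estimated correlation). Cd74, a chaperone of antigen presentation, fell from 199 ± 94.2 to 41.4 ± 13.5 CPM, Mrc1, the mannose receptor of border macrophages, from 336 ± 194 to 94.0 ± 69.9 CPM and Dab2 from 391 ± 198 to 109 ± 37.3 CPM. At a cluster resolution of 2.0 these nuclei split into 356 microglia and 32 perivascular macrophages, of which Cd74, Mrc1 and Dab2 were leading genes. The macrophages were 15 of 143 fed and 17 of 245 fasted nuclei, and the 3 genes were too low to be tested in the other 356, so their fall was not shown in microglia themselves. The oligodendrocyte gene Prr5l rose from 37.2 ± 3.59 to 248 ± 216 CPM. UMIs of the myelin gene Mbp per microglial nucleus were 0.189 in fed and 0.563 in fasted libraries. In microglia edgeR called 27 genes higher and 11 lower of 3237 tested. DESeq2 called 1, which was Fkbp5, and edgeR called 0 with doublets kept or with the stricter filter on nuclei, and 2 at a cluster resolution of 2.0. Without the first fasted library 12 genes were called and without the second 93. Without the second fed library Cd74 (edgeR adjusted p = 0.738), Mrc1 (0.574) and Dab2 (0.325) did not pass, nor did Mrc1 (0.450) and Dab2 (0.0616) without the first fasted one.

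Committed oligodendrocyte precursors and fibroblasts were examined in 121 and 91 nuclei. At a cluster resolution of 2.0 the 91 split into 62 fibroblasts and 29 mural cells of blood vessels, led by Pdgfrb, Rgs5 and Abcc9, so the values for fibroblasts are those of a mixture. In committed precursors Edil3, which encodes a secreted matrix protein, rose from 280.5 ± 128 to 969.5 ± 104 CPM (edgeR adjusted p = 4.50e-05) and the nuclear receptor gene Rora rose from 357 ± 32.9 to 893 ± 157 CPM (edgeR adjusted p = 0.00352). Abcb10, a mitochondrial transporter gene, fell from 254 ± 25.4 to 43.3 ± 15.1 CPM (edgeR adjusted p = 0.00255). Of 12 genes of myelin structure and oligodendrocyte identity 1 fell, also adjusted over the list alone. This was the connexin gene Gjc3 (3682 ± 819.8 to 2355 ± 319.5 CPM). The list's median was -0.31 (camera adjusted p = 0.0341; adjusted p = 0.606 with an estimated correlation), and it did not pass without the second fed library (camera adjusted p = 0.0761) or the first fasted library (0.312). In committed precursors edgeR called 13 genes higher and 22 lower of 2228 tested, and DESeq2 called 2, which did not include Edil3 (adjusted p = 0.145), Rora, Abcb10 or Gjc3. Rora did not pass without the second fasted library (edgeR adjusted p = 0.136), nor Abcb10 without the first fasted (0.0532), nor Gjc3 without the second fed (0.387), the first fasted (0.564) or the second fasted library (0.0765). Leaving out the first fed, second fed, first fasted and second fasted library gave 83, 32, 7 and 24 calls in this class. In fibroblasts edgeR called 0 of 575 genes, with 58 at an unadjusted p under 0.05, and DESeq2 called 0, with 39. Without the same libraries fibroblasts gave 9, 15, 24 and 0 calls (the last with 40 at an unadjusted p under 0.05), so that the first count over both classes was 92. The genes with the smallest p there were Dach1 (1092 ± 292 and 29.7 ± 42.0 CPM), Clint1, Lrrtm4, Nrxn3 and Prkg1 (edgeR adjusted p = 0.105 for each).

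Ttr and Ptgds, which passed in several classes, are described here, and they were not the only such genes. Zbtb16 rose in neurons (36.6 ± 0.302 to 47.6 ± 3.79 CPM, edgeR adjusted p = 6.86e-04), as it did in oligodendrocytes, astrocytes and oligodendrocyte precursors. Ttr, which encodes transthyretin and is made in quantity by the choroid plexus (ENSMUSG00000061808, chromosome 18 from 20665280 to 20674321), was tested in 4 classes and passed in each. It fell from 20.4 ± 0.570 to 0.514 ± 0.0605 CPM in neurons and from 31.8 ± 5.32 to 1.13 ± 0.867 CPM in oligodendrocytes. In astrocytes it gave 46 UMIs in the fed and 0 in the fasted libraries, at least 16.4-fold lower against a floor of 3 counts over the group, and in oligodendrocyte precursors 32 and 0, at least 10.0-fold lower. In precursors the call was lost with DESeq2 (adjusted p = 0.761) and without either fed library (edgeR adjusted p = 0.346 and 0.147). In microglia, committed precursors and fibroblasts, where it was too low to be tested, Ttr gave 8, 11 and 11 UMIs in the fed and 0, 0 and 1 in the fasted libraries. Ptgds (ENSMUSG00000015090, chromosome 2 from 25466709 to 25470046) rose in oligodendrocytes from 1173 ± 36.9 to 3019 ± 230 CPM, in astrocytes from 142 ± 47.4 to 339 ± 23.2 CPM and in microglia from 309 ± 12.4 to 917 ± 305 CPM. It also rose in oligodendrocyte precursors (log2 fold change 1.00) and did not pass in committed precursors or fibroblasts (edgeR adjusted p = 0.703 and 0.826). DESeq2 did not call Ptgds in microglia or oligodendrocyte precursors. In microglia edgeR also did not call it with doublets kept or with the stricter filter on nuclei. Ptgds UMIs per nucleus went from 3.17 to 7.75 in oligodendrocytes, from 0.944 to 1.78 in neurons, from 0.409 to 0.894 in astrocytes and from 2.78 to 5.09 in fibroblasts, and RNA from oligodendrocytes was not excluded for the rise in the other classes. This set of classes for Ptgds was chosen after the values were seen.

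To ask whether the fast acted differently on oligodendrocytes and neurons, the difference of the effects was tested. The log2 increase was larger in oligodendrocytes by 2.79 for Sgk1 (SE 0.09; edgeR adjusted p = 4.58e-207), by 2.80 for Fkbp5, by 2.55 for Hif3a, by 2.46 for Plin4 and by 1.09 for Zbtb16. Klf9 (0.90) and Usp2 (1.43) differed in the same direction. Among lower genes, Hsp90ab1 (-0.59), Hmgcs1 (-0.60) and Hspa5 (-0.65) fell further in oligodendrocytes, with edgeR adjusted p = 8.91e-12, 1.45e-05 and 6.04e-04. No difference was called for Ttr, Zmym1 and Nsdhl (edgeR adjusted p = 0.837, 0.910 and 0.571). In all 570 genes had a higher and 523 a lower effect in oligodendrocytes of 18481 tested, and 726 differed without the second fasted library. The balance of the 2 directions was not stable: with size factors by the median ratio 514 were higher and 593 lower, and without the second fed library 366 and 394. Against astrocytes, 114 of 12906 genes differed. Gli2 (4.15) and Hif3a (1.96) were higher in oligodendrocytes and Zfhx3 (-1.77) in astrocytes, while Fkbp5 (edgeR adjusted p = 0.838) and Sgk1 (0.352) were not called. Sgk1 was too low to be tested within astrocytes, so this does not show a like rise there. Its gain was 0.0197 UMIs per nucleus in astrocytes and 0.598 in oligodendrocytes.

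Receptor and peptide transcripts were mapped over the neuronal clusters, which were partly defined by these genes. Gfral, the receptor of GDF15, had UMIs in 19.3 ± 3.68% of nuclei in neuronal cluster 21 (SD over 4 libraries), a catecholaminergic-like cluster of 175 nuclei, and in 0.0908% of oligodendrocytes. The calcium-sensing receptor gene Casr (18.1 ± 2.36%) and Glp1r (13.8 ± 6.58%) were seen in the same cluster, against 0.176 and 0.136% of oligodendrocytes. There 1.14% of nuclei, 2 in all, held both Gfral and Glp1r where independence gives 2.59%. Shares with an SD were means over libraries, while those of pairs and of thinned nuclei in clusters pooled the nuclei of all libraries. Calcr and Ramp3, which form an amylin receptor, had UMIs in 37.6 ± 12.6% and 24.1 ± 2.98% of the 142 nuclei of cluster 25, a glutamatergic-like cluster, and 15.5% held both where independence gives 8.68%. Gcg was seen in 90.4 ± 6.74% of the 29 nuclei of cluster 34, and Lepr, the leptin receptor gene, in 68.2 ± 17.3% of them. In cluster 28, catecholaminergic-like with 118 nuclei, Dbh, an enzyme of noradrenaline synthesis, was seen in 34.6 ± 7.92%, and Prlh, which encodes prolactin-releasing peptide, in 8.65 ± 0.974%. Cartpt was seen in 53.6 ± 4.14% of nuclei of cluster 22 and Gal in 56.1 ± 4.41% of cluster 11, both glutamatergic-like. As background, oligodendrocytes had UMIs of Calcr in 0.113%, Ramp3 in 0.226%, Gcg in 0.172%, Lepr in 0.878%, Dbh in 0.201%, Prlh in 0.0960%, Cartpt in 1.74% and Gal in 2.35% of nuclei. Oligodendrocytes were shallower (median 2357 UMIs) than neurons (7837). With every nucleus thinned to 2000 UMIs, which left out 59 neurons (30 fed, 29 fasted) and 1577 oligodendrocytes (623 fed, 954 fasted), the pooled share of Gfral went from 18.9 to 15.1% of cluster 21, and its mean in oligodendrocytes was 0.0765%. Other pooled shares fell further: from 17.7 to 9.88% for Casr and 13.7 to 6.98% for Glp1r in cluster 21, 35.2 to 17.99% for Calcr and 24.6 to 12.9% for Ramp3 in cluster 25, 89.7 to 69.0% for Gcg and 65.5 to 27.6% for Lepr in cluster 34, 33.9 to 15.3% for Dbh and 8.47 to 3.39% for Prlh in cluster 28, 53.4 to 38.4% for Cartpt in cluster 22 and 56.2 to 30.4% for Gal in cluster 11. Of 53 genes 50 had a higher share in neurons than in oligodendrocytes in each of the 4 libraries, and 35 did after thinning, with Gal and Prlh not among them. Gipr was seen in 4.08% of oligodendrocytes and 2.32% of neurons.

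**Figure D4:**
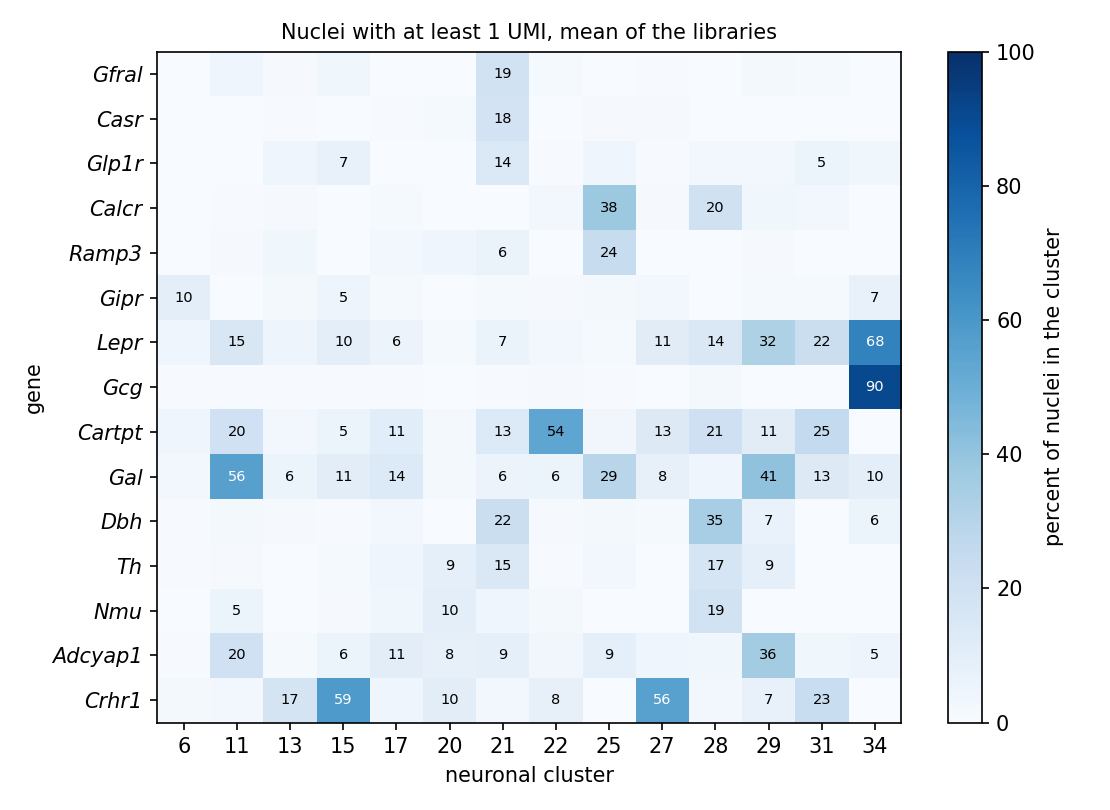
Percent of nuclei with at least 1 UMI of each gene (vertical) in selected neuronal clusters (horizontal), as the mean of the libraries, with values of 5 and above printed. Among the clusters shown, Gfral, Casr and Glp1r are highest in cluster 21, Calcr and Ramp3 in cluster 25, and Gcg in cluster 34. Cluster 33 is left out, because 1 library held 1 of its 33 nuclei, and its mean for Calcr was 41.4 ± 43.9%.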

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

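The tests of the gain in neurons, of Mt1, of the markers of other classes, of depth, of the most abundant genes and of matched neuronal clusters were chosen only after the result was seen, while the comparison with the highest gain in another class and the test of Ttr were chosen before.

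Results that differed between groups of cells were singled out for a closer look. The effect of fasting differed between oligodendrocytes and neurons for 1093 genes and between oligodendrocytes and astrocytes for 114 genes, by the interaction test of edgeR. The first count ranged from 726 to 813 when a library was left out, and the second was not repeated under alternatives. In simulated data the test within astrocytes recovered 40.3% of genes changed 2-fold and that within oligodendrocytes 70.1%, so the lower count against astrocytes cannot be read as a smaller difference.

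In the first pattern weighed, the rise of 17 glucocorticoid-responsive genes in fasted oligodendrocytes by a median of 1.80, all 17 stayed past the threshold after thinning to equal totals, which argues against depth, and the share of UMIs outside the 10 most abundant genes differed by 0.0226 on the log2 scale, which argues against a few abundant genes. Free RNA should add about the same UMIs to every nucleus, but neurons gained a median of 0.0846 of the gain in oligodendrocytes (quartiles 0.0294 to 0.125), which argues against it. The gain was not corrected for depth, and neurons held 10122 and 9277 UMIs per nucleus in the fed and 9063 and 8544 in the fasted libraries, which lowers it. The fewer UMIs per nucleus of 4 of the 17 genes in fasted neurons are therefore not evidence against free RNA. Klf9, 1 of the 4, measured 35.1 ± 1.09 CPM in fed and 36.0 ± 1.76 CPM in fasted neurons. The test set beforehand came out on the side of free RNA. Its median was 0.820 times the highest gain in another class, and 10 of 17 genes gained more elsewhere. A response in that class also gives this, but only 3 of the 10 (Fkbp5, Hif3a and Mt1) passed there. Of the other 7, Cdkn1a, Klf9, Bcl6 and Usp2 did not pass there. Nfkbia, Sult1a1 and Pnpla2 were too low to be tested there. For these 7 the higher gain was not explained. Markers of astrocytes, both kinds of precursors, microglia and fibroblasts gained in oligodendrocytes a median of at most 0.00154 of their level in their own class. This argues against more fragments of those classes in the fasted libraries. Markers of neurons were not tested, so fragments of neurons are not covered. The smallest gain of the 17 genes was 0.192 of the highest gain elsewhere. That is a share of a gain and not of a level, so it does not measure what fragments would need to bring. A share of fragments that was the same in both groups would pass on a rise in the other class without a gain of its markers. The gain of the markers cannot decide on such a share. For Mt1, free RNA and a rise in oligodendrocytes cannot be told apart, since neurons gained 0.718 of the gain in oligodendrocytes (0.602 to 0.894 between libraries). For the others a response to the fast, an unchanged share of fragments of other cells and more fragments of neurons stay open. So does any difference in handling, on which the labels are silent.

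The second pattern was the large number of genes called in neurons while the share of 17 of 35 neuronal clusters differed between the groups. With equal numbers of nuclei per cluster the called genes kept a median of 0.891 of their log2 fold change (quartiles 0.710 to 1.03 over 2503 genes), and 1290 stayed past the threshold. The lower quartile of 0.710 argues against an uneven sample of the 35 clusters as the whole cause. Matching cannot decide on a shift of kinds of neurons inside a cluster, since it equalises only the clusters. Within single clusters Zmym1 was lower and Las1l higher in 26 of 26, but these genes were picked from those with the most calls. Whether the uneven sample gave part of the change cannot be told apart from a change within neurons. The median fell just short of the bound set for excluding this part. Of the genes, 272 (10.9%) lost most of their change and 35 changed sign, Gal and Cartpt among the latter. The clusters were drawn with the called genes, so matching may also have removed part of a change within neurons.

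The third pattern was lower Ttr in fasted nuclei of several classes. Ttr UMIs per fed nucleus lay between 0.0559 and 0.239 over 7 classes, a ratio of 4.27, against 32.2 in choroid plexus nuclei. Free Ttr RNA from choroid plexus and expression in these cells cannot be told apart. The fasted libraries held no choroid plexus nuclei, and 4.27 lay just above the bound of 4 set for free RNA. Enpp2, more abundant still in choroid plexus nuclei (43.1 UMIs), went only from 0.141 to 0.1003 UMIs in astrocytes. Enpp2 cannot decide, since fed oligodendrocytes held 3.44 UMIs of it and the ratio in free RNA from the cytoplasm is unknown. Clic6, at 2.31 UMIs in choroid plexus nuclei, went from 0.00344 to 0 UMIs in astrocytes and from 0.00755 to 0 in oligodendrocyte precursors. In neurons it went only from 0.0240 to 0.0222. Outside neurons the UMIs of Clic6 were too few to decide. A different amount of choroid plexus in the dissected blocks, different handling and a response to the fast could each give these values, and none was tested further.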

How the results depend on the processing

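The alternatives with a 1.5-fold test, matched neuronal clusters, capped voom weights, a crossed pairing and neurons clustered again were chosen only after the result was seen. With size factors by the median ratio, 246 of 246 values of named genes, of which 196 were calls, kept their direction and their side of the threshold. The replicate block ended 2 calls, no filter on low counts 16, DESeq2 66 and the 1.5-fold test 130, each of 196. Leaving out a library ended 45 of 196 calls without the first fed, 42 of 195 without the second fed, 40 of 192 without the first fasted and 34 of 195 without the second fasted library. Thinning ended 31 of 191 calls, kept doublets 13 of 191, the stricter filter on nuclei 9 of 189, a resolution of 2.0 2 of 190 and the stricter count filter 0 of 150. A gene that an alternative did not test has no value there. Of 67 calls in neurons, matched clusters ended 18 and reversed 2 more: Cartpt to -0.00308 (edgeR adjusted p = 0.991) and Gal to -0.0226 (0.941). A lone library of a group was assumed to vary like the others.

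Counts that changed by more than 1.5-fold follow by setting. The 1.5-fold test asks for a larger change, and for the other settings the cause was not tested. Removing nuclei did not always lower a count: the stricter filter on nuclei gave more calls in the other classes. DESeq2 called 746 genes in neurons, 808 in oligodendrocytes, 46 in astrocytes, 0 in oligodendrocyte precursors (113 at an unadjusted p under 0.05, against 605 with edgeR), 1 in microglia and 2 in the other classes, where edgeR called 35. It gave an adjusted p to other sets of genes than edgeR, from 1363 in astrocytes to 19128 in oligodendrocyte precursors, so the counts are not over like sets. The 1.5-fold test called 34, 181, 17, 1, 13 and 2 in the same order. With neuronal clusters matched 1419 genes were called in neurons. Thinning libraries gave 64 in astrocytes, 6 in oligodendrocyte precursors, 9 in microglia and 14 in the other classes. Microglia gave 65 calls with no filter on low counts, 10 with the stricter one, 0 with doublets kept (113 at an unadjusted p under 0.05), 0 with the stricter filter on nuclei (120 at an unadjusted p under 0.05) and 2 at a resolution of 2.0. In the other classes no filter gave 15, the stricter count filter 68, doublets kept 54 and the stricter filter on nuclei 130. That filter also left 1 class whose share differed, where 2 had.

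The replicate block gave 56 calls in the other classes and 1150 in single neuronal clusters. Libraries with the same number share nothing else that the labels name, and the correlation of their deviations from the group means across genes, which are not independent replicates, lay between -0.0403 and 0.000835 in 6 classes and was -0.118 in fibroblasts. A crossed pairing was run in fibroblasts alone and gave 22 calls there, or 57 with the 35 calls of committed precursors, which were not paired again.

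For gene lists, camera with an estimated correlation called 0 of 73 (15 with the preset one), with 3 at an unadjusted p under 0.05, and with capped voom weights it also called 0, with 5. Fry called 6, of which 5 were among the 15. Capped weights with the preset correlation kept the 15 and called 4 more, 19 in all. In oligodendrocyte precursors these were the glucocorticoid-responsive genes, higher, and 2 lists that were lower. The lower ones were the endoplasmic reticulum and integrated stress response (camera adjusted p = 9.29e-04) and the heat shock chaperones (0.0102). The last was the circadian clock in oligodendrocytes, higher (0.0498). Leaving out a library gave ranges of 22 to 132 calls in astrocytes, 6 to 19 in oligodendrocyte precursors, 12 to 93 in microglia, 24 to 92 in the other classes, 957 to 1077 in single neuronal clusters and 726 to 813 for the difference between oligodendrocytes and neurons. The number of classes whose share differed ranged from 0 to 2.

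Depth sets what was detectable. In simulated data genes changed by 2-fold were recovered in 76.1% of cases in neurons and in 19.4% in microglia, so a gene not called in microglia cannot be read as unchanged.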

Other observations

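The gene lists and their tests were set beforehand, while the genes named here and the clustering of neurons without the called genes were chosen only after the result was seen.

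Some core clock genes differed in fasted oligodendrocytes. Per1 rose from 19.7 ± 1.87 to 50.7 ± 0.3499 CPM (edgeR adjusted p = 6.33e-12), Cry1 from 7.51 ± 2.24 to 16.8 ± 5.03 CPM, Cry2 from 40.2 ± 0.429 to 56.3 ± 2.70 CPM and Tef from 78.9 ± 0.859 to 102 ± 0.515 CPM, while Nr1d2, which encodes the repressor REV-ERB beta, fell from 34.3 ± 1.79 to 23.8 ± 0.146 CPM. These were 4 that rose and 1 that fell of 16 clock genes, also adjusted over the list alone, with 11 not called. The list did not pass the planned test (camera adjusted p = 0.0638, or 0.606 with an estimated correlation). With capped voom weights, chosen after seeing the data, the list passed narrowly (camera adjusted p = 0.0498, or 0.536 with an estimated correlation). In neurons Per1 rose from 7.68 ± 0.971 to 11.2 ± 0.0531 CPM and Cry1 and Cry2 rose as well, while Rora, Arntl and Nfil3 fell, 3 and 3 of 19, also adjusted over the list alone (camera adjusted p = 0.989). With equal nuclei per neuronal cluster only Per1 and Cry1 passed (edgeR adjusted p = 0.0286 and 0.0439), and the other 4 did not (0.114 to 0.234). The hour at which each group was sampled is not given in the sources used here.

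Genes of myelin moved in both directions in oligodendrocytes, 8 up and 5 down of 20, or 8 and 7 adjusted over the list alone (camera adjusted p = 0.939), with a median of 0.03 and a mean of -0.01. Mobp rose from 1057 ± 3.11 to 1412 ± 8.10 CPM and Tspan2 from 471 ± 13.8 to 608 ± 3.80 CPM, while the connexin gene Gjc3 fell from 1381 ± 19.3 to 1038 ± 23.5 CPM and Mag from 996 ± 20.1 to 804 ± 18.7 CPM. The insulin receptor gene Insr rose from 127 ± 2.72 to 159.6 ± 10.8 CPM and Foxo3 from 33.9 ± 1.64 to 47.7 ± 0.498 CPM, while Igf1r fell from 287 ± 7.18 to 242 ± 2.96 CPM and Irs2 from 68.2 ± 6.45 to 50.1 ± 0.473 CPM (2 up and 2 down of 15 genes of insulin and FOXO signalling, or 3 and 2 adjusted over the list alone; camera adjusted p = 0.989). In autophagy Ulk2 rose from 159 ± 2.65 to 197 ± 2.16 CPM and Lamp2 from 84.3 ± 3.04 to 108 ± 0.494 CPM, while Wipi1 fell by 0.27 on the log2 scale, in all 5 up and 1 down of 21, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.182). Nucb2, the precursor of the satiety peptide nesfatin-1, fell from 36.5 ± 0.893 to 16.5 ± 1.98 CPM. In astrocytes the glucose transporter gene Slc2a3 rose from 20.6 ± 2.99 to 53.2 ± 5.49 CPM and Glul, which makes glutamine, from 351 ± 3.10 to 587 ± 43.2 CPM. Cirbp, an RNA-binding protein gene induced by mild cold, rose in neurons (49.3 ± 1.22 to 66.6 ± 0.519 CPM) and oligodendrocytes (46.6 ± 9.03 to 75.2 ± 5.86 CPM), and Rbm3, which is induced in the same way, did not pass in either (edgeR adjusted p = 0.373 and 0.164).

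Not every glucocorticoid-responsive gene was called. In oligodendrocytes 4 of 21 were not, namely Tsc22d3, Nedd9, Mt2 and Mertk (edgeR adjusted p = 0.113, 0.224, 0.153 and 0.367), and in neurons 14 of 23 were not. Tsc22d3 measured 156 ± 5.45 and 139 ± 5.61 CPM in oligodendrocytes and was also not called in neurons, astrocytes or microglia (edgeR adjusted p = 0.649, 0.866 and 0.934).

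Among 35 neuronal clusters the share of nuclei was higher in the fasted libraries for 11 and lower for 6 by edgeR. Among the lower ones, cluster 4 went from 10.5 ± 0.221 to 1.18 ± 0.295% of neurons (edgeR adjusted p = 2.26e-07). The serotonergic-like cluster 33 went from 0.634 ± 0.164 to 0.113 ± 0.102% (edgeR adjusted p = 0.00716). Foxp2 was among the leading genes of cluster 4, and Tph2 led cluster 33. Clusters drawn without the genes called in neurons or in single neuronal clusters (2671 genes) numbered 25, of which 5 were higher and 5 lower. A cluster led by Npsr1 and Stpg2 made up 8.20 ± 0.0864% of fed and 4.45 ± 0.340% of fasted neurons (edgeR adjusted p = 0.0144), and a glutamatergic-like cluster with Calcr and Ramp3 made up 1.88 ± 0.464 and 3.19 ± 0.0632% (edgeR adjusted p = 0.0411). The catecholaminergic-like cluster with Gfral and Casr did not pass (1.70 ± 0.456 and 2.14 ± 0.570%; edgeR adjusted p = 0.370).

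Between neurons and oligodendrocytes 167 genes were higher in both, where independent calls would give 58.2, and 309 lower in both, where they would give 97.9. Another 77 were called in opposite directions. Both classes came from the same libraries, so the calls are not independent.

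A cluster of 51 nuclei matched none of the markers well enough to be named.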
